A study of Mus musculus with 9 samples.

How the data were processed

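The series measured RNA of mouse mammary epithelial cell preparations on 9 Affymetrix whole-transcript arrays, with 3 arrays in each of 3 groups. Per the labels' protocols, cells were freed from mammary fat with collagenase and taken before trypsin (untrypsinized), after trypsin (trypsinized), or after trypsin and a mock pass through a cell sorter (mock sorted). Total RNA was extracted with a kit and labelled with biotin, per the labels. The labels call the 3 arrays of a group biological replicates and do not say which animals they came from, so p-values measure only the spread between these samples, part of which may be technical.

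The deposited values are intensities on a linear scale, in 35512 rows, with 1 value per row and array. The background correction, the summary of probes into rows and the scaling between arrays are not given in the sources used here. The submitters' processing notes name limma. Median intensity per array was 345 to 408 over all rows, and the number of arrays limits the precision. Values were tested as log2 of the intensity plus a pseudocount of 1, so fold changes of dim genes are understated.

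Rows were named through a table of the platform annotation, which can be old. Of the rows, 21789 had 1 gene symbol, 1621 had several and 12102 were not listed there and stay unnamed. Symbols of 21698 single-symbol rows were updated by gene number with the RefSeq gene table of the GRCm38.p6 assembly, and no coordinates are given because the files name no build. The row with the highest mean over the 9 arrays stood for each gene, which gave 19938 genes, of which 999 had more than 1 row.

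Tests used limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 9 arrays, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p of 0.05 or below and a fold of at least 1.5. The submitters' design text gives both numbers without saying whether p was adjusted, so the unadjusted reading was run as an alternative. The comparison of mock sorted with untrypsinized arrays is not in that text. A moderated F test asked which genes differed among the 3 groups. Of 33 gene lists fixed before the data were examined, the 32 with at least 5 measured members were tested with camera, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The remaining list had 1 measured member and was not tested.

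Genes named below follow a rule fixed at the same stage. They were drawn from the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out predicted genes, clone names and small RNA symbols, and up to 4 members of each list with the smallest p. Not every gene that the rule gives is named, so the named genes are a selection.

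The model was tested on simulated data with the real gene means and spreads of 19938 genes. For the trypsinized against untrypsinized comparison it recovered 96% of 50 genes changed 2-fold and 44% of 50 genes changed 1.5-fold, with 3 false calls. For mock sorted against trypsinized it recovered 92% and 44%, with 1 false call, and for mock sorted against untrypsinized 100% and 48%, with 1 false call. The simulated noise was independent between genes and between arrays, so false calls from correlated genes or paired arrays were not measured.

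The replicate numbers recur in each group. Deviations from the group mean correlated across genes at 0.53, 0.29 and 0.29 between trypsinized and mock sorted arrays of the same number. The highest correlations of these mock sorted arrays with a trypsinized array of another number were -0.31, 0.16 and 0.13. The numbers were therefore taken to pair these arrays, most clearly in replicate 1. This pairing comes from the values, not from the labels.

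Alternatives covered the threshold, scaling, filters on dim genes, the row that stands for a gene, the variance model, array weights, the arrays in the fit, the replicate block and leaving out each array. Another pseudocount, scaling over the tested genes alone, a blocked fit of 6 arrays, and leaving out the replicate-1 arrays of the trypsinized and mock sorted groups were added after seeing the data.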

Results

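RNA levels were compared among mouse mammary epithelial cell preparations at successive stages of isolation. The cells came from C3H females aged 8 to 9 weeks and were released from fat tissue with collagenase. Untrypsinized cells had met only collagenase, trypsinized cells were then digested with trypsin, and mock sorted cells also passed a mock fluorescence-activated cell sort. Each group had 3 arrays. Log2 intensities correlated at 0.993 to 0.997 between arrays of a group, at 0.987 to 0.993 between untrypsinized and trypsinized arrays, at 0.990 to 0.995 between trypsinized and mock sorted arrays, and at 0.981 to 0.986 between untrypsinized and mock sorted arrays. Changes below are log2 differences of group means with their standard errors (SE), n = 3 arrays per group, and adjusted p-values from limma.

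The comparison of trypsinized with untrypsinized cells asked which transcripts differ after the trypsin digestion. Of the markers of Schwann cells, which wrap peripheral nerves, 5 of 10 were called lower after trypsin, and of the endothelial markers 5 of 19, in lists whose camera calls were lost with an estimated correlation (adjusted p = 0.330 and 0.374). Without untrypsinized replicate 3, 3 and 2 were called. The T cell genes Cd8b1 and Lat were called higher, with calls that depended on single arrays. Cdh19, a cadherin of the Schwann lineage, fell by 1.73 on the log2 scale (SE 0.08, adjusted p = 0.000115), from 9.12 ± 0.12 to 7.39 ± 0.08 (mean ± SD of log2 intensity). Gjc3, a gap junction protein of myelinating glia, fell by 1.43 (SE 0.10) and Gpm6a, a neural membrane glycoprotein, fell by 1.38 (SE 0.08). In all, 292 of 19938 genes were called changed, of which 106 were higher and 186 lower. More genes were higher than lower with no minimum fold (2766 and 2289) and with a replicate block (193 and 185). Over every row, named or not, 1227 rows were higher and 214 lower, and these are rows, not genes. Of the 106 higher genes, 25 were small RNA genes and 12 were olfactory or vomeronasal receptor genes.

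Among the fixed marker lists, the Schwann cell list had 5 of 10 measured members called lower, with a median log2 change of -0.56 (camera adjusted p = 2.05e-06; adjusted p = 0.330 with an estimated correlation). Mbp, a myelin protein, fell by 0.88 (SE 0.06). The endothelial list had 5 of 19 members called lower at a median of -0.44 (camera adjusted p = 6.31e-11; adjusted p = 0.374 with an estimated correlation). Tek, the angiopoietin receptor, fell by 0.79 (SE 0.08) and Vwf, the von Willebrand factor gene, fell by 0.67 (SE 0.07). Without untrypsinized replicate 3 the Schwann list had 3 members called lower and the endothelial list 2, and without untrypsinized replicate 1 the endothelial list had 8. The list of pericytes and vascular smooth muscle had 2 of 11 members called lower, or 1 without untrypsinized replicate 3, at a median of -0.37 (camera adjusted p = 1.71e-06; adjusted p = 0.330 with an estimated correlation), and Rgs4 fell by 0.68 (SE 0.09). The fibroblast list had a median of -0.26 with 1 of 22 members called lower, Ogn (camera adjusted p = 2.16e-08; adjusted p = 0.374 with an estimated correlation). In the skeletal muscle list 4 of 19 members were called lower, among them Ckm, the muscle creatine kinase, which fell by 1.07 (SE 0.19), and in the adipocyte list 2 of 17, among them Car3, which fell by 0.75 (SE 0.14). Without untrypsinized replicate 1 the muscle list had 2 called lower, and the adipocyte list had 1 without untrypsinized replicate 3 or trypsinized replicate 1. Both lists had a camera adjusted p of 0.00159 (adjusted p = 0.396 and 0.374 with an estimated correlation). The epithelial-mesenchymal transition list had 3 of 18 members called lower (camera adjusted p = 0.00461; adjusted p = 0.396 with an estimated correlation), among them Zeb2, a transcription factor, which fell by 0.70 (SE 0.11). Counts adjusted over the list alone were the same as those over all genes for each list named for this comparison. In all, 17 of 32 lists were shifted by camera, 5 up and 12 down, and 0 with an estimated correlation.

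The luminal epithelium list had a median log2 change of 0.07, with 0 of 18 members called and 7 higher at an unadjusted limma p under 0.05 (camera adjusted p = 0.00461; adjusted p = 0.374 with an estimated correlation). The sign of this median depended on the scaling of arrays. With arrays set to a common median over all rows, the luminal median was -0.06 and the median over all genes moved from 0.04 to -0.09, and the list stayed 0.03 to 0.13 above all genes under each scaling tried. The basal and myoepithelial list had a median of -0.09 with 0 of 22 members called and 11 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000540; adjusted p = 0.396 with an estimated correlation and 0.0559 after quantile normalization). Of the stress lists, immediate early genes, which respond within minutes to many stimuli, had 0 of 31 members called, with 11 higher and 5 lower at an unadjusted p under 0.05 (camera adjusted p = 0.118). At an adjusted p of 0.05 or below, 7 were higher and 4 lower, all under 1.5-fold. The fry test, which takes a list by itself, called this list up (adjusted p = 0.00517), while its median of 0.06 ranged from -0.07 to 0.07 over the scalings tried. Heat shock chaperones had 0 of 17 called, with 3 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.686). The list of ERK feedback and EGF family ligands had 0 of 18 called, with 11 higher and 3 lower. Its median of 0.16 was 0.02 to 0.17 under each scaling tried (camera adjusted p = 0.0180, and 0.374 with an estimated correlation). The interferon list had a median of -0.10 with 0 of 18 called (camera adjusted p = 0.00461, and 0.396 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets had 2 of 27 members called higher, Tnf and Lif, and its median of 0.10 was -0.03 with arrays set to a common median (camera adjusted p = 0.0189; adjusted p = 0.396 with an estimated correlation). Without trypsinized replicate 1 its median was 0.03 and its camera call was lost (adjusted p = 0.0637). Without trypsinized replicate 2 or 3 its median was 0.16 and 0.18. Lif, a cytokine, rose by 0.61 (SE 0.05), and was under the minimum fold without untrypsinized replicate 3 at 0.57, without trypsinized replicate 2 at 0.58 and with a common median at 0.47. Tnf, another cytokine, rose by 0.73 (SE 0.05, adjusted p = 0.000213). The oxidative phosphorylation list had a median of -0.13 with 0 of 26 members called and 19 lower at an unadjusted p under 0.05 (camera adjusted p = 1.71e-06; adjusted p = 0.374 with an estimated correlation).

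Genes with the largest rises included Cd8b1, a T cell co-receptor chain, at 1.75 (SE 0.50, adjusted p = 0.0365), Lat, an adaptor of T cell receptor signalling, at 1.51 (SE 0.43, adjusted p = 0.0365), Clec2e at 1.37 (SE 0.06, adjusted p = 0.000115) and Muc4, a membrane mucin, at 0.97 (SE 0.07, adjusted p = 0.000259). Trav7d-4, a T cell receptor segment, was also called higher (adjusted p = 0.00854, at most 0.0312 under the settings that gave it a value), at levels of 4.59 ± 0.24 in untrypsinized and 6.23 ± 0.53 in trypsinized arrays. Both lay below the mean level of olfactory receptor genes, 6.55. It may not be above background, so no size is given for its rise. The lymphocyte list had a median log2 change of 1.04 with 0 of 16 members called and 9 higher at an unadjusted p under 0.05 (camera adjusted p = 0.00649; adjusted p = 0.547 with an estimated correlation). Without mock sorted replicate 1, 7 members were called higher. Without trypsinized replicate 1 the median was 0.58. Its level was uneven: the list median was 10.47 in trypsinized replicate 1, 9.08 and 8.97 in the other trypsinized arrays, and 8.29 to 8.36 in the untrypsinized arrays. Without trypsinized replicate 1 the change of Cd8b1 was 1.31 (adjusted p = 0.102) and that of Lat was 1.05 (adjusted p = 0.0826). Both calls were also lost without any of the untrypsinized arrays, with an adjusted p of 0.0530 to 0.110 for Cd8b1 and 0.0676 to 0.0928 for Lat, and that of Cd8b1 also without trypsinized replicate 2 (adjusted p = 0.0618) or mock sorted replicate 2 (adjusted p = 0.0511). With a robust variance trend both calls were lost as well (adjusted p = 0.0676 for Cd8b1 and 0.0670 for Lat). The split of calls moved with scaling: quantile normalization over all rows gave 57 higher and 279 lower genes, a common median over all rows 55 and 376, and quantile normalization over the tested genes 80 and 227.

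**Figure D1:**
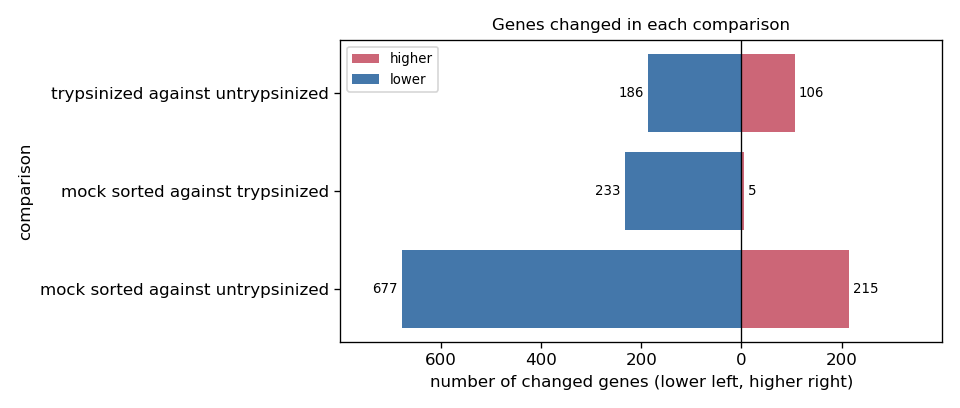
Number of genes called changed in each comparison, with lower genes to the left of 0 and higher genes to the right. The bars stand at 186 lower and 106 higher for trypsinized against untrypsinized, 233 and 5 for mock sorted against trypsinized, and 677 and 215 for mock sorted against untrypsinized.

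The comparison of mock sorted with trypsinized cells asked what the sorter passage adds. Nearly every called gene was lower: 233 genes fell and 5 rose among 19938. Aqp7, a glycerol channel of fat cells, fell by 1.55 (SE 0.14, adjusted p = 0.000436), Car3 fell by 1.44 (SE 0.14), Aplnr, the apelin receptor, fell by 1.39 (SE 0.08), Igf2, a growth factor, fell by 1.37 (SE 0.05) and Sele, the endothelial adhesion molecule E-selectin, fell by 1.33 (SE 0.07). The genes that rose were the vomeronasal receptor genes Vmn1r16 and Vmn1r38, Phxr4, and the small RNA genes Mir325 and Snora74a, which fall outside the naming rule and were named after their values were seen. Phxr4 rose by 0.65 (SE 0.07, adjusted p = 0.000900). Vmn1r16 was at 3.92 ± 0.09 in trypsinized and 4.70 ± 0.13 in mock sorted arrays, below the mean level of vomeronasal receptor genes, 6.02, so it may not be above background. It was under the minimum fold with a pseudocount of 16.

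The endothelial list had 17 of 19 members called lower, at a median log2 change of -1.02 or 2.03-fold lower (camera adjusted p = 1.53e-31; adjusted p = 0.0842 with an estimated correlation). Cldn5, a tight junction protein of vessels, fell by 1.32 (SE 0.08), from 10.69 ± 0.01 to 9.37 ± 0.12, and Tek fell by 1.29 (SE 0.08). The list of pericytes and vascular smooth muscle had 5 of 11 members called lower at a median of -0.56, and it was called under both forms of camera (adjusted p = 2.16e-14; adjusted p = 0.0455 with an estimated correlation). Rgs5, a pericyte regulator of G protein signalling, fell by 1.12 (SE 0.08) and Des, the intermediate filament desmin, fell by 0.98 (SE 0.09). The Schwann cell list had 3 of 10 members called lower (camera adjusted p = 3.07e-06; adjusted p = 0.123 with an estimated correlation), and Cdh19 fell, to a mock sorted level of 6.21 ± 0.10 that lay below the mean level of olfactory receptor genes, 6.55, so no size is given for its fall. The adipocyte list had 4 of 17 called lower, at a median of -0.16 with 6 members higher (camera adjusted p = 0.000118, and 0.225 with an estimated correlation). Among those called, Fabp4, a fatty acid carrier, fell by 1.10 (SE 0.07) and Cd36, a fatty acid receptor, fell by 1.18 (SE 0.07). The fibroblast list had a median of -0.17 with 0 of 22 members called and 9 lower at an unadjusted p under 0.05 (camera adjusted p = 6.95e-06; adjusted p = 0.428 with an estimated correlation). The macrophage and myeloid list had a median of -0.19 with 1 of 22 members called lower, Cd209f (camera adjusted p = 4.22e-05; adjusted p = 0.434 with an estimated correlation). This median was -0.12 without trypsinized replicate 1, -0.29 without mock sorted replicate 1 and -0.10 without mock sorted replicate 2.

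Luminal epithelium had a median of 0.06 with 0 of 18 members called and 2 higher at an unadjusted p under 0.05 (camera adjusted p = 0.000908; adjusted p = 0.255 with an estimated correlation), and hormone-sensing luminal cells a median of 0.12 with 0 of 11 called and 6 higher (camera adjusted p = 7.27e-06; adjusted p = 0.0876 with an estimated correlation). The basal and myoepithelial list had a median of -0.14 with 0 of 22 called and 14 lower (camera adjusted p = 6.18e-09; adjusted p = 0.189 with an estimated correlation). The Wnt and Notch list was called under both forms of camera (adjusted p = 1.68e-07; adjusted p = 0.0455 with an estimated correlation), with 1 of 26 members called lower, Procr, an endothelial and stem cell receptor, which fell by 1.08 (SE 0.12). In the list of inflammatory cytokines and NF-kB targets 2 of 27 members were called lower (camera adjusted p = 0.000981; adjusted p = 0.293 with an estimated correlation), and Il6, a cytokine, fell by 0.83 (SE 0.06). The other, the chemokine Cxcl10, lost its call without trypsinized replicate 1, 2 or 3 (adjusted p = 0.0611, 0.0656 and 0.0733) and without mock sorted replicate 2 (log2 change -0.47), which left 1 member called. In the interferon list 2 of 18 were called lower (camera adjusted p = 1.98e-05; adjusted p = 0.224 with an estimated correlation), and Ifit3 fell by 0.69 (SE 0.10). The other, Ifit1, was under the minimum fold without mock sorted replicate 2, at -0.57. The basement membrane list had a median of -0.17 with 0 of 19 called and 15 lower at an unadjusted p under 0.05 (camera adjusted p = 5.96e-09; adjusted p = 0.144 with an estimated correlation). Immediate early genes had 0 of 31 members called and 7 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0948). The fry test called this list down (adjusted p = 0.0312), while its median of -0.02 ranged from -0.04 to 0.02 over the scalings tried. Heat shock chaperones had 0 of 17 called and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.323). Counts adjusted over the list alone were the same for each of these lists. In all, 16 of 32 lists were shifted, 2 up and 14 down, and the lists of pericytes and of Wnt and Notch genes were the only camera calls in any comparison that held with an estimated correlation.

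**Figure D2:**
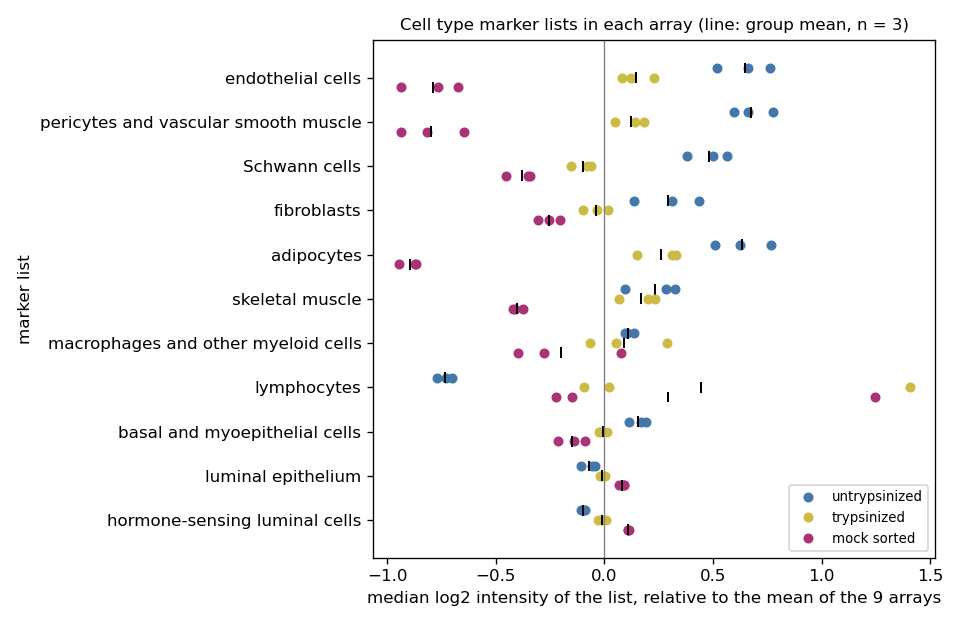
Median log2 intensity of each cell type marker list in each array, relative to its mean over the 9 arrays, with points for arrays, colours for groups and black lines for group means. The endothelial list lies between 0.52 and 0.76 in untrypsinized arrays and between -0.94 and -0.67 in mock sorted arrays, and the lymphocyte list stands at 1.40 and 1.25 in replicate 1 of the trypsinized and mock sorted groups. The median of levels need not follow the changes of the members. Adipocyte points lie at 0.15 to 0.33 in trypsinized and -0.95 to -0.87 in mock sorted arrays. The list's median change at the mock sort was only -0.16, with 6 of 17 members higher. Skeletal muscle points lie at 0.07 to 0.23 and -0.42 to -0.37, against a median change of -0.07.

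Mock sorted and untrypsinized cells, which differ by both steps, differed in 892 genes, with 215 higher and 677 lower. With no minimum fold 4189 genes were higher and 3588 lower, and over every row, named or not, 2234 rows were higher and 801 lower. Gjc3 fell by 2.43 (SE 0.10), and Cdh19 fell as well (adjusted p = 1.34e-06), with no size given because of its mock sorted level. The endothelial list had 18 of 19 members called lower at a median of -1.46 (camera adjusted p = 6.82e-18; adjusted p = 0.212 with an estimated correlation), and Tek fell by 2.08 (SE 0.08). Pericytes and vascular smooth muscle had 7 of 11 called lower (camera adjusted p = 9.60e-10), and Schwann cells 6 of 10 (camera adjusted p = 4.96e-06), each with an adjusted p = 0.212 with an estimated correlation. Adipocytes had 8 of 17 called lower (camera adjusted p = 0.000296) and fibroblasts 4 of 22 (camera adjusted p = 9.60e-10), each with an adjusted p = 0.290 with an estimated correlation. Without untrypsinized replicate 1 or 3, 2 fibroblast members were called lower. Luminal epithelium and hormone-sensing cells had 0 of 18 and 0 of 11 members called, with 15 and 8 higher at an unadjusted p under 0.05, and 1 hormone-sensing member was called higher without untrypsinized replicate 1 or mock sorted replicate 2. Their medians were 0.14 and 0.19 (camera adjusted p = 0.000296 and 0.00104; adjusted p = 0.283 and 0.229 with an estimated correlation), and that of luminal epithelium was -0.01 with arrays set to a common median over all rows. Counts adjusted over the list alone were the same for these lists. In all, 18 of 32 lists were shifted by camera, 2 up and 16 down, and 0 with an estimated correlation. Muc4 rose by 1.24 (SE 0.07), and Lama5, a laminin chain of epithelial basement membranes, rose by 0.61 (SE 0.04), while Lama4, a laminin chain of vessel walls, fell by 0.89 (SE 0.06). Lama5 was under the 1.5-fold minimum without untrypsinized replicate 1, at 0.58, with array weights, at 0.58, and with a common median over all rows, at 0.46. Quantile normalization over all rows gave 116 higher and 861 lower genes, and a common median over all rows 92 and 1028.

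A moderated F test found 6612 of 19938 genes that differed among the 3 groups. Of the 186 genes lower after trypsin and the 233 lower after the mock sort, 93 were lower in both steps, where independent lists would share 2.17 (Fisher's exact test, two-sided p = 3.59e-135, genes not being independent of each other). A further 2 genes were higher in both steps and 1 was higher and then lower. Simulated unchanged groups that share the trypsinized arrays gave a mean of 0 genes, and 7.02 in any direction at an unadjusted p, where the data gave 99. No gene was changed in the simulation, so few could be called in either step, and it left out the pairing of arrays. It therefore does not test the overlap of changed genes. The shared arrays, too few to split, enter the steps with opposite signs, so their chance values act against a fall in both. Of the 233 genes lower after the mock sort, 232 had a log2 change below 0 at the trypsin step, 209 of them with an adjusted p of 0.05 or below.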

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

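The test of a general background was chosen only after the result was seen, and the spreads set beside it and beside the test of nuclear RNA were added after those values were seen. Rows without a gene name entered above only in the settings over all rows. They were brighter in trypsinized than in untrypsinized arrays by a median of 0.17 on the log2 scale, against 0.04 for named rows. Their median log2 intensity was 7.24 to 7.34 in untrypsinized, 7.52 to 7.58 in trypsinized and 7.62 to 7.66 in mock sorted arrays. After quantile normalization over all rows the excess over named rows was 0.0809, compared with 0.13 before, so the deposited scaling cannot be told apart from a change in the RNA. Unnamed rows were brighter after trypsin by 0.115 more than olfactory and vomeronasal receptor genes of the same brightness, with 0.06 to 0.17 over the 9 pairs of arrays, which leaves genomic DNA or a general background open. The 8 measured nuclear-retained RNAs had a median change of 0.0359 relative to all genes (bootstrap SE 0.15). Of these, Malat1 at 0.41, Mir17hg at 0.49 and Pvt1 at 0.28, named after their values were seen, were higher at a limma adjusted p of 0.00984, 0.00185 and 0.00169, under 1.5-fold, and none was lower at an adjusted p of 0.05 or below. The bound set beforehand, a median under 0.05, was met by less than this spread, so a larger share of nuclear RNA stays open as well.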

How the results depend on the processing

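Settings added after seeing the data were the pseudocount of 16, scaling over the tested genes alone, the blocked fit of 6 arrays and leaving out both replicate-1 arrays. Counts of changed genes in the order trypsin step, mock sort and both steps were 292, 238 and 892, and most settings kept them within 1.5 times. Dropping the minimum fold gave 5055, 931 and 7777 genes and an overlap of 701 in place of 96. Leaving out genes below the median intensity gave 129, 158 and 470, with fewer genes tested. Testing every row, named or not, called 1441 and 3035 rows, not genes, for the trypsin step and both steps, of which 1227 and 2234 were higher. The cause of the changes was otherwise not tested. With 1 array left out, the counts ranged over 257 to 332, 214 to 281 and 857 to 957, the F test over 4618 to 6332 genes and the overlap over 80 to 115. The unadjusted reading of the threshold gave 366, 266 and 932 genes. Without both replicate-1 arrays the counts were 321, 274 and 943.

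The lists called by camera numbered 17, 16 and 18 of 32. With an estimated correlation 0, 2 and 0 were called, so most list calls rest on the preset correlation. The fry test called 21, 18 and 23, but it asks whether a list's own genes changed, not whether they changed more than other genes. Its counts are therefore no check on the camera calls.

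With a replicate block the counts were 378, of which 193 were higher, 240 and 954, the F test gave 6548 genes and the overlap was 95. Whether the numbers also pair the untrypsinized arrays stays open. Their same-number deviations correlated at 0.11, 0.04 and -0.04 with trypsinized and at 0.32, 0.18 and 0.06 with mock sorted arrays. Not every array correlated best with its own number, but in replicate 1 the highest other values were -0.02 and -0.16. A blocked fit of the 6 trypsinized and mock sorted arrays alone called 251 genes. The block changed no list or named gene call at the mock sort. Elsewhere it added calls of Cd3e, Cd3g and Cd4 at trypsin and of the lymphocyte list over both steps.

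No named gene changed direction. With a common median over all rows, the medians of the called inflammatory, adhesion and luminal lists at trypsin and of the luminal list over both steps were below 0. Relative to all genes, of the called lists at trypsin only ribosomal proteins changed sign. Genes below a filter have no value under it. Of 121 called results of named genes, 27 lost their call under at least 1 setting.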

Other observations

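Of the tests of the endothelial and lymphocyte patterns, those of dilution, of fewer endothelial cells, of a faulty array and of the trypsin step were chosen only after the result was seen. So were the look at gene families, the splits at an unadjusted p, the splits that part the pairs and the reading of the share of called endothelial genes as open.

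Gene families outside the fixed lists were described at the trypsin step and had no set test. Small nucleolar RNA genes, which guide modification of ribosomal RNA, had a median log2 change of 0.23, with 10 of 51 called higher, and stayed above 0 under each scaling. MicroRNA genes had a median of 0.16 with 15 of 300 called higher and 1 lower, and olfactory receptor genes a median of 0.11 with 10 of 1027 called higher and 2 lower. Each median was below 0 under at least 1 scaling, with lowest values of -0.01 and -0.08. Relative to all genes, the microRNA median stayed above 0, at 0.03 to 0.12, while that of olfactory receptor genes ranged from -0.04 to 0.07.

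The median log2 change of the endothelial list at the mock sort was -1.02. It was -1.01 after quantile normalization and -1.01 after removing a linear trend on brightness and on gene span, which argues against scaling or such a trend as the whole cause. The list fell by more than the macrophage list, with a difference of medians of -0.84. The permutation p of 1e-05, the smallest the permutations can give, shuffled list members as if independent. It does not measure the spread between arrays. With 1 array left out, the macrophage median was -0.29 to -0.10, above the endothelial -1.02, and its lowest member in the main fit was at -0.72. A list median can miss a fall of some members: the adipocyte median was -0.16, with 6 of 17 members higher, while Fabp4 fell by 1.10. The difference of medians therefore cannot decide whether all cells other than epithelium were diluted alike. That 89.5% of the members were called lower is what fewer endothelial cells would give, but lower expression in the same cells would give it too, so this hypothesis stays open.

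Lymphocyte genes were high in replicate 1 of both the trypsinized and the mock sorted group, by a median of 1.35 and 1.36 over the other arrays of the group. A fault of a single array would not raise both, and the lower of these differences was 1.35. This restates how the pattern was picked and is no separate test. Lymphocytes in the replicate-1 preparation, alone or with other immune cells, are a candidate source: 26 lymphocyte genes outside the list were higher as well, by 0.94 and 0.97, none of them in a fixed list, and the macrophage and myeloid list, relative to its mean over the 9 arrays, stood at 0.29 in trypsinized replicate 1 against -0.07 and 0.05 and at 0.08 in mock sorted replicate 1 against -0.40 and -0.28. The untrypsinized arrays stood at 0.09 to 0.13 for the macrophage and myeloid list, above mock sorted replicate 1. List members with high means over the 9 arrays, named after their values were seen, included Ccr7, Cd79b and Ptprc, at 12.23, 11.41 and 11.31 in trypsinized replicate 1. Ccr7 was at 10.50 in untrypsinized replicate 1, above 9.83 in trypsinized replicate 3 and 9.62 in mock sorted replicate 3. An effect of trypsin itself stays open, since the mean list level was higher in all 3 trypsinized than in all 3 untrypsinized arrays (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow).

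Of 100 splits of the 9 arrays into groups of 3, only the real 1 gave as many genes by the F test, 6612, and the highest of the others gave 4644. This share of 1 in 100 counts against chance only if arrays can be exchanged, and the pairing of trypsinized and mock sorted arrays goes against that. Of 280 splits, 124 part all 3 of the trypsinized and mock sorted pairs that the numbers give, and of 100 of these, the real one included, only the real one gave as many genes, with 4464 the highest of the others. For the comparisons of 3 against 3 arrays, the 10 splits are too few for a share under 0.05. The real split gave 292, 238 and 892 genes, and the highest of the others gave 0 each time. At an unadjusted p with the minimum fold, in fits of the 6 arrays, the real split gave 390, 264 and 946 and the highest of the others 32, 154 and 33. The numbers were taken to pair the mock sorted and trypsinized arrays. Of the other splits that part all 3 pairs, as the real one does, the highest gave 11 genes, so the 154 came from a split that keeps a pair together.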
